A study of Mus musculus with 12 samples.

How the data were processed

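Gene expression was measured on 12 one-colour Agilent whole mouse genome arrays, in helper T cells from C57BL/6 mice aged 7 weeks. Per the labels, the cells were activated for 65 hours through CD3 and CD28 with antibodies, kept in IL-2 for 48 hours, transfected by electroporation on days 1 and 4, and harvested on day 5, 24 hours after the second transfection. Cells lacking Dgcr8, a cofactor of Drosha in microRNA processing, received miR-29b or a control miRNA. Wild-type cells received miR-29 inhibitors or control inhibitors. Each of the 4 groups held 3 arrays, from mice numbered 2, 3 and 4 within each genotype.

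The deposited scanner files gave spot intensity in arbitrary units. Per the file headers they were extracted with Agilent Feature Extraction 10.5.1.1, which subtracts background from each spot and does not scale arrays to each other. The authors also deposited a table of log2 values, for which the labels name limma without a version and state no further steps. Its columns had nearly equal distributions, with a largest difference between sorted columns of 0.18 (log2). Their order followed that of the median spot signal before background subtraction. The scanner values were used for the results below and the authors' table served as an alternative.

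Each array held 45018 spots, of which 1639 were controls, and 41174 distinct probes. The processed signal was converted to log2, the 75th percentile of the array was subtracted, and spots of one probe were averaged. A probe was kept when it was well above background on at least 3 of the 12 arrays, which left 32200 probes, 21083 of them with a gene symbol. The brightest probe stood for each gene, giving 14701 genes, and 4976 of these had more than 1 kept probe. Between 27287 and 31405 probes per array were well above background and 0 spots were saturated. With 3 arrays per group, the number of arrays limits the precision.

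Group means were compared with limma 3.58.1 in R 4.3.3 (data.table, version 1.17.8), with all 12 arrays in one fit of 4 groups. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. They measure the spread between mice within groups, pooled over all 4 groups, and both arrays of a mouse entered this fit as if independent. The p-values of a comparison thus also rest on the arrays of the other groups. Log2 differences between 2 arrays of a group had an SD of 0.71 to 0.95 in Dgcr8-deficient cells and 0.47 to 0.75 in the wild type. The comparisons were miR-29b against control in Dgcr8-deficient cells, inhibitors against control in wild-type cells, the controls of both genotypes against each other, and the difference between the first 2 effects. The genotype comparison also differed in the kind of control oligonucleotide, so genotype and control type cannot be separated. A log2 fold change is given with its standard error, and a fold against a group near background is given as a lower bound. That bound sets the group near background to at least the lowest signal well above background, and it leaves out sampling error.

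The pairing of arrays by mouse was checked on residual expression. Arrays of one mouse correlated within the Dgcr8-deficient genotype at 0.652, 0.613 and 0.753, and within the wild type at 0.468, 0.722 and 0.43. Equal mouse numbers across genotypes correlated at 0.239, -0.326 and -0.353 among controls, so those were not treated as pairs. Dgcr8-deficient mouse 4 and wild-type mouse 3 shared a slide. Their control arrays correlated at 0.537, and their miR-29b and inhibitor arrays at 0.654. These correlations therefore cannot tell a shared mouse from a shared slide or scan day. A fit with the mouse as a block was also run, and its values are called blocked where they are given. Both arrays of a mouse shared a slide and a scan day, over 4 slides and 2 scan days, and slide and scan day were also used as blocks. P-values with the mouse as a block measure the spread within mice, and with slide as a block mostly that spread. The scanner software marked 1458 spots as outliers on the miR-29b array of mouse 3, against 68 to 193 on the other 11 arrays.

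Before the data were examined, 26 gene lists and the rule for named genes were fixed. The rule took 10 key genes, the 8 largest rises and 8 largest falls among genes past the threshold whose groups did not overlap, and up to 4 members of each list with the smallest p. The lists were curated miR-29 targets, the Th1 and cytotoxic, Th2, Th17, Treg and Tfh programs, naive and memory markers, T cell activation, interferon-stimulated genes, cell cycle, p53 targets, apoptosis regulators, DNA methylation and demethylation, collagens and extracellular matrix, microRNA biogenesis and effectors, curated targets of other T cell microRNAs, heat shock and unfolded protein response, ribosomal protein genes, glycolysis, cholesterol and fatty acid synthesis, CD4 T cell identity, and markers of CD8 T cells, B cells, NK cells, myeloid and dendritic cells, and erythroid cells and platelets. Lists were tested with camera at its preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a comparison. The lists shared members: 3 of the curated miR-29 targets were in the Th1 list, 5 in the apoptosis list, 6 in the DNA methylation list and 13 in the extracellular matrix list.

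The fits were tested on simulated data with 14188 genes and 100 changed genes of each size. Without a block, 24% of changes of log2 1 and 71% of changes of log2 2 were recovered for miR-29b, and 22% and 69% for the inhibitors. With the mouse as a block, recovery was 56% and 88% for miR-29b, and 56% and 86% for the inhibitors. The difference between both effects was recovered for 4% and 45% of genes without a block, and 34% and 79% with one. False calls made up 10.4% of calls in the simulated genotype comparison.

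Alternatives covered background correction by normexp with an offset of 50, quantile normalization, the filter on dim probes, the variance model, the arrays in the fit, the choice of probe, the authors' table, the blocks, and leaving out each array in turn. Normexp was run on the median spot signal in place of the mean signal, which was not used here. Added after seeing the data were that change to normexp, fits without Dgcr8-deficient mouse 3, fits on the first scan day only, the mouse block combined with the authors' table or with leaving out mouse 3, and the look-up of miR-29b calls in the inhibitor comparison. The shift of genes by miR-29 sites in their 3' untranslated regions was not analysed here, since it needs transcript sequences. Probes without a gene symbol were tested apart from the named genes. Of the genes that met the rule for naming, several are not reported here by name, and they stayed in every test and count.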

Results

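The data were 12 arrays of helper T cells on day 5 of culture, 24 hours after transfection, with 3 mice for each of 4 groups. Dgcr8-deficient cells received miR-29b or a control miRNA, and wild-type cells received miR-29 inhibitors or control inhibitors. The first comparison asks what miR-29b changes in cells short of their own microRNAs, and the second what blocking miR-29 changes in normal cells. Between 27287 and 31405 of 41174 probes per array were well above background. Levels are log2 signals relative to the 75th percentile of the array, changes are log2 fold changes ± SE from limma (n = 3 per group), and adjusted p-values come from the same fit.

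Dgcr8, the deleted gene, had levels of -1.19 to -0.10 on the 6 Dgcr8-deficient arrays and -0.12 to 1.04 on the 6 wild-type arrays. Among controls it was lower in Dgcr8-deficient cells by a log2 change of -1.04 ± 0.38, which did not pass the threshold (adjusted p = 0.0777) but did with scan day as a block (adjusted p = 0.00175). Of 13 alternative settings 4 called it and 9 did not (limma, adjusted p up to 0.219). Within the slides that held both genotypes the difference was -0.56 and -1.14. The position of the probe relative to the deleted part is not known. Dgcr8 differed by -0.0034 between miR-29b and control. Y-linked transcripts were near background on both arrays of Dgcr8-deficient mouse 3 (median at most -7.87) and at -0.32 or higher on the other 10 arrays.

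**Figure D1:**
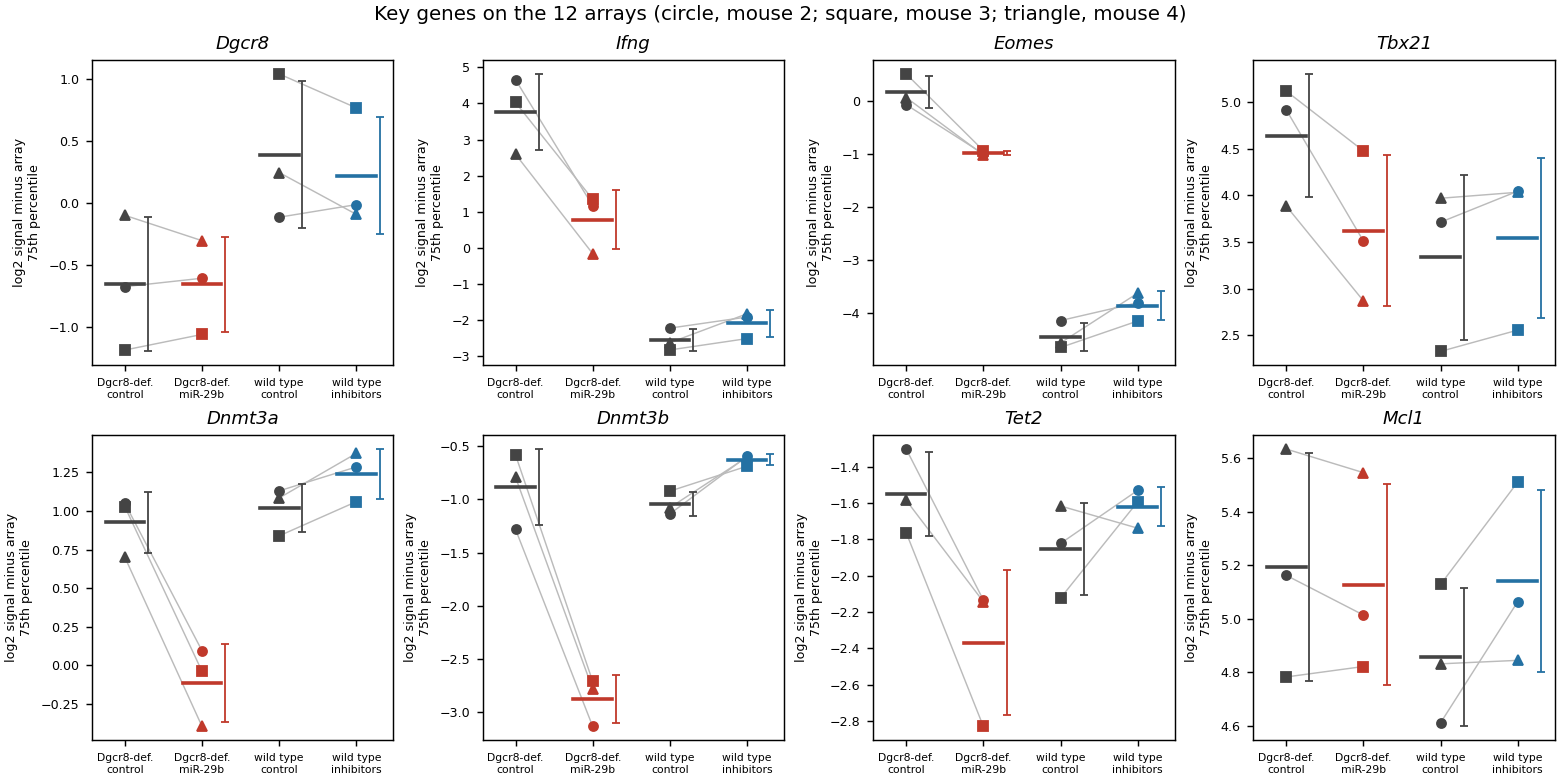
Levels of 8 key genes on the 12 arrays, as log2 signal minus the 75th percentile of the array, with lines joining the arrays of one mouse, bars at group means and error bars of 1 SD. Ifng, Eomes, Dnmt3a and Dnmt3b fell with miR-29b in each of 3 mice, by -2.98, -1.15, -1.04 and -1.99 on average, and the vertical scales differ between panels.

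miR-29b lowered Ifng, the gene of the cytokine interferon gamma, in Dgcr8-deficient cells by -2.98 ± 0.52 (adjusted p = 0.0184), with changes of -3.49, -2.68 and -2.75 in the 3 mice. Eomes, a T-box transcription factor that promotes Ifng expression, fell by 1.15 ± 0.21 on the log2 scale (adjusted p = 0.0226). Both de novo DNA methyltransferases fell: Dnmt3b by -1.99 ± 0.20 (adjusted p = 0.00291) and Dnmt3a by -1.04 ± 0.19 (adjusted p = 0.0198). Tbx21, which encodes the Th1 regulator T-bet, changed by -1.02 ± 0.59 and did not pass without a block (adjusted p = 0.515), whereas it passed with the mouse as a block (adjusted p = 0.00924). Tet2, an enzyme of DNA demethylation, showed -0.82 ± 0.23 (adjusted p = 0.106, blocked 0.0175). Mcl1, an antiapoptotic gene, showed -0.07 ± 0.28 on its brighter probe, and -0.94 on the other, and neither passed. The 3 Dnmt3a probes gave -1.82, -1.04 and -0.41, the last not past the threshold. Drosha and Dicer1 showed -0.15 and -0.29 and did not pass.

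Beside these genes, the largest falls were in Ahrr (-2.66), the repressor of the aryl hydrocarbon receptor, Ifi30 (-2.57), a lysosomal thiol reductase of antigen processing, Fbn1 (-2.52), which encodes fibrillin, Cd93 (-2.42), Dcakd (-2.21), Igfbp7 (-2.16) and Batf2 (-2.11). Fbn1 remained lower but not past the threshold with normexp (-1.17), and Cd93 showed -0.27 on its brightest probe that was well above background on all arrays. The largest rises were in Art4 (2.72) and Oit3 (2.65), and in genes near background in the controls: Ric3 (2.72), Adipoq (2.67), Ces2e (2.42), Chl1 (2.41), Hdac11 (2.23) and Alb (2.23), which were at least 2.97-, 2.18-, 1.74-, 2.33-, 4.08- and 2.29-fold higher. With normexp the rises were 0.13 for Ric3, 0.58 for Adipoq, 0.38 for Ces2e, 0.49 for Chl1, 0.72 for Hdac11 and 0.50 for Alb, none past the threshold, and 2.04 for Art4 and 2.09 for Oit3, both past it. In the authors' values Ric3 changed by -0.27, so the lower bounds hold for the scaled signal alone.

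Of 14701 genes, 336 passed, 130 higher and 206 lower with miR-29b, and 2055 had an unadjusted p under 0.05. With the mouse as a block 3074 passed (1555 higher, 1519 lower), among them all 336, and slide and scan day as blocks gave 2466 and 1840. Higher genes made up 38.7% of calls, and 25.1% with normexp (60 higher, 179 lower). On the 6 arrays of the comparison alone 0 genes passed in limma, with 1358 at an unadjusted p under 0.05. Without one array the count was 103 (control of mouse 2), 145 (control 3), 183 (control 4), 159 (miR-29b array of mouse 2), 139 (miR-29b 4) and 276 (miR-29b 3), and it was 116 without mouse 3. Of 34 named genes past the threshold, 12 passed in all 6 of these single-array fits, Dnmt3b, Ifi30, Bak1 and Apaf1 among them. Ifng was lost without control 2, control 3 or miR-29b 4 (adjusted p up to 0.0722), Dnmt3a without the same arrays (up to 0.0886), and Eomes in 5 of 6 fits (up to 0.078).

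Curated miR-29 targets were lower as a group: 9 of 53 fell, 0 rose and 44 did not pass, with a median of -0.21, and 10 fell when adjusted over the list alone. Dnmt3b, Narf (-1.43 ± 0.16), Fbn1 and Ifng had the smallest p. The list passed camera (adjusted p = 1.31e-05) and fry (0.0105), and not with an estimated correlation (adjusted p = 0.162). Its median was -0.31, -0.19 and -0.25 in the 3 mice, and without one array between -0.36 (control 2) and -0.18 (miR-29b 2), past camera each time. In the DNA methylation list, 3 of 17 genes fell and 14 did not pass (5 lower adjusted over the list alone), Dnmt3a and Dnmt3b, which add methyl groups, and Tdg (-1.86 ± 0.41), which excises oxidised methylcytosine. That list passed camera (adjusted p = 0.0144), and neither with the mouse as a block (0.106) nor with an estimated correlation (adjusted p = 0.217). It also did not pass with quantile normalization or the authors' values. With the mouse as a block 19 curated targets fell and 3 rose, and 6 DNA methylation genes fell and 3 rose.

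In the Th1 and cytotoxic list 5 of 28 genes fell, 0 rose and 23 did not pass (7 lower adjusted over the list alone, camera adjusted p = 4.17e-05, adjusted p = 0.283 with an estimated correlation). The median of -0.45 became -0.12 without miR-29b 2 and -0.81 without miR-29b 3. Besides Ifng and Eomes these included Il18rap (-1.86 ± 0.27), a subunit of the interleukin 18 receptor, and Il12rb2 (-1.36 ± 0.25), a subunit of the interleukin 12 receptor. Of 35 interferon-stimulated genes 1 fell, the GTPase Iigp1 (-0.999 ± 0.22, adjusted p = 0.0464), and 34 did not pass (6 lower adjusted over the list alone). The median of that list was -0.40 (camera adjusted p = 3e-05, adjusted p = 0.283 with an estimated correlation), and -0.64, 0.03 and -0.45 in mice 2, 3 and 4, and -0.25 without miR-29b 4. The Th2, Th17, Treg and Tfh lists, naive and memory markers and T cell activation genes had 0 members past the threshold (1 higher and 1 lower in the Treg list and 0 in the others adjusted over the list alone) and camera adjusted p of 0.618, 0.832, 0.549, 0.403, 0.303 and 0.816. In the blocked fit 9 Th1 and cytotoxic genes and 12 interferon-stimulated genes fell and 1 of each rose, and rises and falls numbered 1 and 0 in the Th2 list, 2 and 2 in the Th17 list, 3 and 1 in the Treg list, 4 and 0 in the Tfh list, 5 and 0 among naive and memory markers and 1 and 0 among T cell activation genes.

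In the cell cycle list, 37 of 39 genes had a negative sign and the median was -0.46 (camera adjusted p = 3.47e-10, fry 0.0356, adjusted p = 0.242 with an estimated correlation). The mitotic kinase gene Aurkb (-0.74 ± 0.15) and the cyclin gene Ccna2 (-0.71 ± 0.15) fell, 37 genes did not pass, and 4 were lower adjusted over the list alone. Aurkb lost its call in 7 of 15 alternative settings and Ccna2 in 5 (limma, adjusted p up to 0.273 and 0.362). With the mouse as a block 21 of the 39 fell. Among apoptosis regulators, the proapoptotic genes Bak1 (-1.87 ± 0.20) and Apaf1 (-1.09 ± 0.17) fell and 21 of 23 did not pass (2 lower adjusted over the list alone). A dimmer Bak1 probe showed -0.06. The list passed camera (adjusted p = 0.0219), and neither with a block (0.0643), nor with an estimated correlation (adjusted p = 0.217), nor without control 2 or miR-29b 3 (adjusted p up to 0.0662), nor with quantile normalization or the authors' values. Its median of -0.13 became 0.04 without miR-29b 4.

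Of 24 cholesterol and fatty acid synthesis genes 2 fell, Hmgcs1 (-1.12 ± 0.24) among them, 22 did not pass, 23 had a negative sign, and 4 were lower adjusted over the list alone. The list passed camera (adjusted p = 0.000131), and not with an estimated correlation (adjusted p = 0.479) or without control 2 (0.0717). Ribosomal protein genes were higher as a group, 40 of 41 with a positive sign and a median of 0.29 (camera adjusted p = 3.12e-05, adjusted p = 0.634 with an estimated correlation), and 0 passed singly. Their median was 0.19 without miR-29b 4, 0.11 with quantile normalization and 0.13 in the authors' values, where the median of all genes was 0.07 here, -0.0043 with quantile normalization and 0.02 in the authors' values. CD4 T cell identity genes had a median of 0.28 (camera adjusted p = 0.00669, adjusted p = 0.306 with an estimated correlation), and 0 of 16 passed (2 higher adjusted over the list alone). That call was lost without control 3 or miR-29b 4 (adjusted p up to 0.133), and the median was 0.43 without control 4.

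Lists that did not pass camera still held 4 genes past the threshold, Fbn1 being given above. The others were Nid1 (-1.41 ± 0.31, at least 2.29-fold), which encodes a basement membrane protein, in the extracellular matrix list (0 higher, 2 lower, 24 not past, adjusted p = 0.842), the phosphatase gene Phlpp2 (-0.87 ± 0.17) in the list of other microRNA targets (1 lower, 35 not past, adjusted p = 0.129), and the stress transcription factor gene Ddit3 (0.82 ± 0.18), the only rise in the heat shock and unfolded protein list (23 not past, adjusted p = 0.934). Nid1 showed -0.07 with normexp. Across 15 alternative settings Phlpp2 was at -0.426 at its smallest and lost its call in 5, and Ddit3 also lost its call in 5. The lists of p53 targets, microRNA biogenesis, glycolysis, CD8, B cell, NK, myeloid, and erythroid and platelet markers had 0 members past the threshold, with camera adjusted p of 0.452, 0.344, 0.618, 0.618, 0.306, 0.743, 0.618 and 0.816, and 1 microRNA biogenesis gene was lower adjusted over the list alone. The last of these had a median of 0.07 and a mean of -0.34. Blocked rises and falls numbered 0 and 6 among apoptosis regulators, 1 and 6 among cholesterol and fatty acid synthesis genes, 3 and 0 among ribosomal protein genes, 5 and 1 among CD4 T cell identity genes, 2 and 2 in the extracellular matrix list, 4 and 4 among targets of other microRNAs, 2 and 3 in the heat shock list, 5 and 1 among p53 targets, 0 and 2 among microRNA biogenesis genes, 3 and 0 for glycolysis, 2 and 0 for myeloid markers and 0 and 1 for erythroid and platelet markers, with 0 for CD8, B cell and NK markers.

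**Figure D2:**
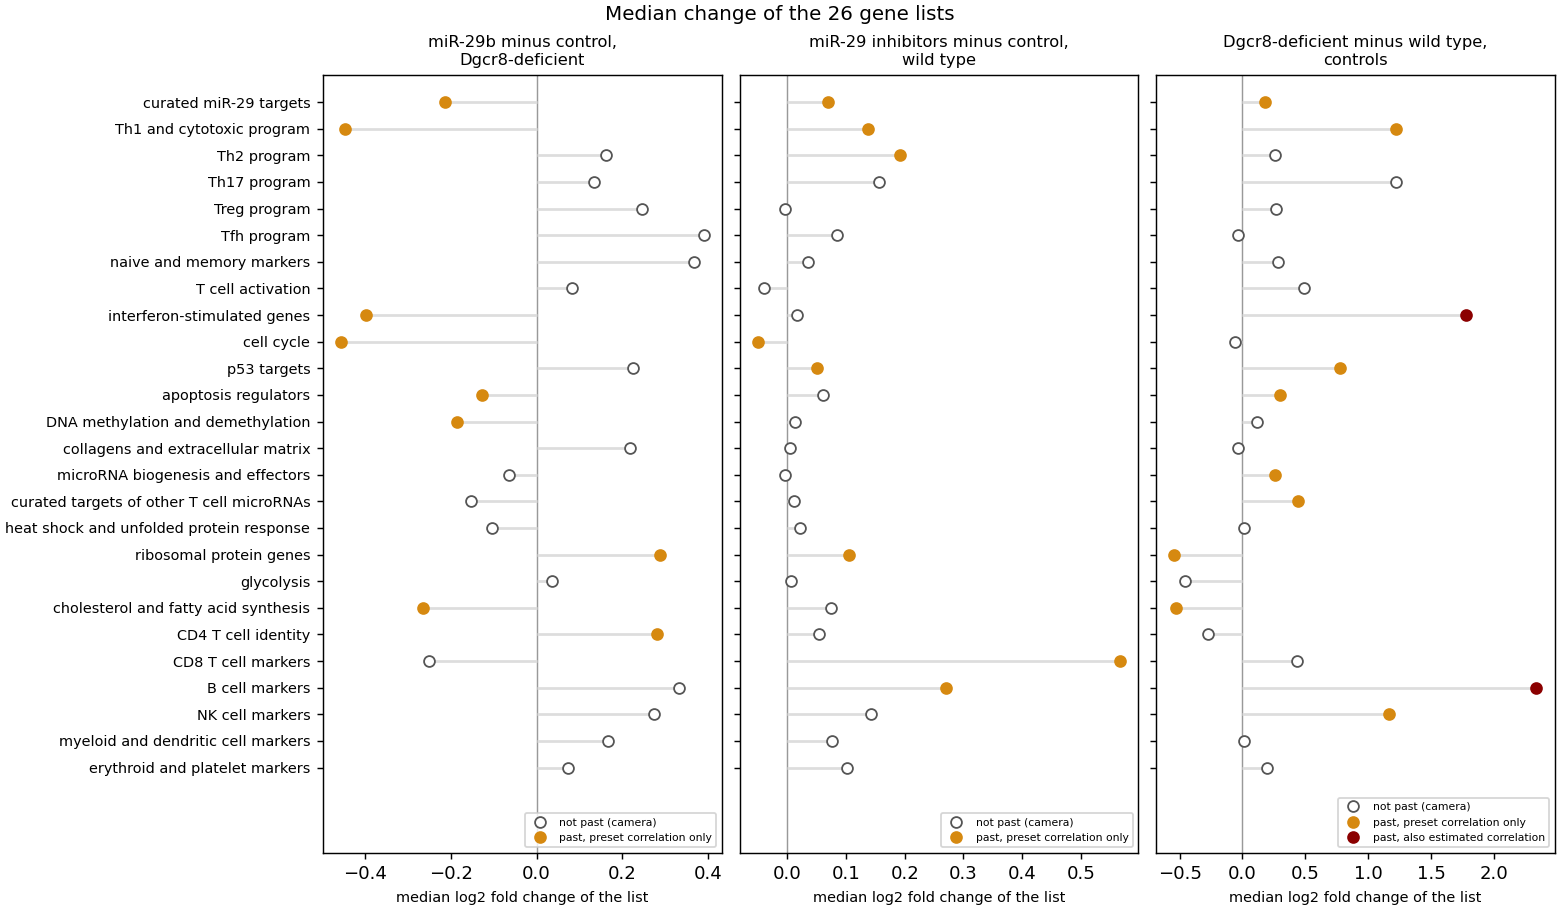
Median log2 fold change of the 26 gene lists in the 3 comparisons, with scales that differ between panels. Filled points passed camera at its preset correlation, which 9, 8 and 11 lists did, and dark red points also passed with an estimated correlation, as only interferon-stimulated genes and B cell markers did between the control groups.

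In wild-type cells, miR-29 inhibitors left every gene short of the threshold. Eomes was at 0.59 ± 0.21 with inhibitors, Ifng at 0.48 ± 0.52, Dnmt3b at 0.42 ± 0.20 and Dnmt3a at 0.22 ± 0.19, each higher in 3 of 3 mice and each with an adjusted p of 1. Tbx21, Mcl1, Tet2, Drosha and Dicer1 were at 0.21, 0.28, 0.23, 0.09 and -0.07, and Dgcr8 at -0.17. The smallest p-values upward belonged to Ocln (3.23), Srd5a1 (0.83), H2-Aa (1.83), Khdc1a (1.14) and Cxcl3 (1.26), and downward to Oas1d (-0.74), Col16a1 (-2.96), Wee2 (-1.51), Olfr120 (-1.36) and Drd4 (-1.61), none past the threshold. Ocln, Cxcl3, Col16a1, Wee2 and Drd4 were near background in one of the groups. With that group set to at least the lowest signal well above background, they differed by 2.73-, 1.55-, 2.72-, 1.92- and 1.61-fold. Since none passed, these folds are no lower bounds of a change. With normexp these 5 were at 0.18, -0.08, -0.68, -0.56 and -0.49, and Khdc1a at -0.16. Across the alternative settings H2-Aa ran from 0.58 to 2.11, Oas1d from -0.745 to -0.252 and Olfr120 from -1.41 to -0.124. In limma 0 of 14701 genes passed, with 63 at an unadjusted p under 0.05. The count was also 0 with mouse, slide and scan day as blocks, with 502, 338 and 160 genes at an unadjusted p under 0.05.

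Small shifts of groups passed camera in this comparison, and none of them passed with an estimated correlation or with fry (0.97). Curated miR-29 targets were higher (median 0.07, 35 of 53 positive, adjusted p = 0.0134, 0.476 with an estimated correlation), as were the Th1 and cytotoxic list (median 0.14, 0.00125, 0.476 estimated) and the Th2 list (0.19, 0.00125, 0.476 estimated). CD8 T cell markers (median 0.57) and B cell markers (0.27) were higher too, both with an adjusted p of 0.00125 and 0.476 with an estimated correlation, and Prf1, the perforin gene, and Maf were at 0.91 and 0.78. With normexp the medians of the CD8 and B cell lists were 0.07 and -0.12 and neither passed (adjusted p = 0.154 and 0.787). p53 targets (median 0.05, adjusted p = 0.0399, 0.591 estimated, 0.213 with a block) and ribosomal protein genes (0.11, 1.33e-05, 0.653 estimated) were higher and cell cycle genes lower (-0.05, 0.0115, 0.663 estimated). Ribosomal medians were 0.33, 0.11 and -0.11 in the 3 mice and -0.02 without the control of mouse 2, and cell cycle medians were 0.03, -0.18 and 0.02. Without one array the lowest p53 median was -0.02 (control 3), the highest cell cycle median 0.09 (inhibitor array 3), and the lowest Th1 and Th2 medians 0.00078 (control 2) and 0.02 (inhibitor array 4). The median of curated miR-29 targets lay between 0.04 (without control 2) and 0.16 (without control 4), the lowest B cell median was 0.18 (control 2), and the highest Th1, Th2, p53 and ribosomal medians were 0.32 (control 3), 0.46 (inhibitor array 3), 0.20 (inhibitor array 3) and 0.18 (inhibitor array 4). None of these 8 lists passed in every fit without one array, with adjusted p between 0.121 and 0.876 at their highest, and 1 to 6 lists passed. The other 18 lists did not pass (adjusted p of 0.241 to 0.995), and 0 members of any list passed, also when adjusted over the list alone without a block. Blocked, 2 Th1 and cytotoxic genes, 1 CD8 marker and 2 B cell markers were higher adjusted over the list alone. Among the 18 lists the median and mean differed in sign for Treg, interferon-stimulated, extracellular matrix, microRNA biogenesis, glycolysis, NK, and erythroid and platelet genes.

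Of the 206 genes that fell with miR-29b, 157 (76.2%) were higher with inhibitors, against 55.2% of all genes. As a set they passed limma's camera (adjusted p = 9.13e-12 over the 2 sets of risen and fallen genes, adjusted p = 0.0352 with an estimated correlation) and not fry (0.137). Of 10 splits of the wild-type arrays, 2 moved as many of the 206 genes one way, the real one included. The highest other moved 169, so a random grouping was not excluded. Of the 130 genes that rose with miR-29b, 77 (59.2%) were higher with inhibitors, and that set did not pass limma's camera (adjusted p = 0.836). Genes called with the mouse as a block showed no such contrast: 922 of the 1519 fallen genes (60.7%) and 968 of the 1555 risen genes (62.3%) were higher with inhibitors, and neither set passed limma's camera (adjusted p = 0.147 and 0.307). Across all 14701 genes, which are not independent replicates, the effects correlated at r = -0.02 (rho = 0.02), and at r = -0.33 across the 336 genes.

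The 2 effects differed for 28 genes, with 25 lower and 3 higher after miR-29b relative to the inhibitor effect, and 1061 at an unadjusted p under 0.05. The difference was -3.21 ± 0.29 for Ifi30, -2.42 ± 0.22 for Srd5a1, a steroid 5-alpha-reductase, -2.41 ± 0.28 for Dnmt3b and -2.15 ± 0.21 for Zbtb34. It was -2.74 for Dcakd, -2.71 for Ccdc28b, -2.60 for Serf1 and -2.55 for Ccn4, and 2.84, 1.96 and 1.75 for Art4, Gpr179 and Lefty1. Narf (-1.75) and Bak1 (-2.07) also passed, while Eomes (-1.74, adjusted p = 0.0551), Ifng (-3.45, 0.114), Dnmt3a (-1.26, 0.106), Tbx21 (-1.23), Tet2 (-1.05), Mcl1 (-0.35), Drosha (-0.24), Dicer1 (-0.22) and Dgcr8 (0.17) did not. Blocked by mouse, Eomes, Ifng, Dnmt3a, Tbx21 and Tet2 passed as well (adjusted p = 0.015, 0.0078, 0.00918, 0.032 and 0.0485) and 888 genes differed, with slide 617 and with scan day 446, and the 28 genes were among them each time. Without single arrays 3 to 51 genes passed, 51 without the miR-29b array of mouse 3 and 3 to 13 without any other, only Ifi30, Srd5a1 and Zbtb34 of 13 named genes passing in all, and 15 passed without mouse 3.

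For the difference between both effects, 9 of 26 lists passed camera, 3 passed fry and 0 passed with an estimated correlation. Of 100 splits within genotypes, 18 gave as many lists past camera, the real one included, so a random grouping was not excluded. The difference passed camera for curated miR-29 targets (2 of 53 lower, 11 adjusted over the list alone, adjusted p = 4.86e-07, 0.0879 with an estimated correlation), the Th1 and cytotoxic list (0 of 28, 6 lower over the list alone, 4.86e-07, 0.191), cell cycle genes (0 of 39, 4.86e-07, 0.348) and interferon-stimulated genes (0 of 35, 1 lower over the list alone, 4.05e-05, 0.348). It also passed for cholesterol and fatty acid synthesis genes (0.000232, 0.465 with an estimated correlation, 0.0604 without control 2), apoptosis regulators (1 of 23 lower, 2 over the list alone, 0.0104, 0.131), DNA methylation genes (1 of 17 lower, 4 over the list alone, 0.0135, 0.191, 0.14 with a block), CD4 T cell identity genes (0.0368, 0.465, 0.104 with a block) and ribosomal protein genes (0.0368, 0.991). The DNA methylation median was -0.08, but 0.07 in the authors' values and 0.06 without the wild-type control of mouse 3. The CD4 list was lost without 6 single arrays (adjusted p up to 0.356) and the ribosomal list without 7 (up to 0.819). Across 16 alternative settings, 10 lost the CD4 call, 9 the ribosomal call and 7 the DNA methylation call. The other 17 lists did not pass (adjusted p of 0.0759 to 0.981) and held 0 genes past the threshold, and the median and mean differed in sign for Th2, Th17 and B cell genes. Blocked, 14 curated miR-29 targets, 10 Th1 and cytotoxic, 5 interferon-stimulated, 5 DNA methylation and 4 each of the cell cycle, apoptosis and cholesterol and fatty acid synthesis genes were lower.

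**Figure D3:**
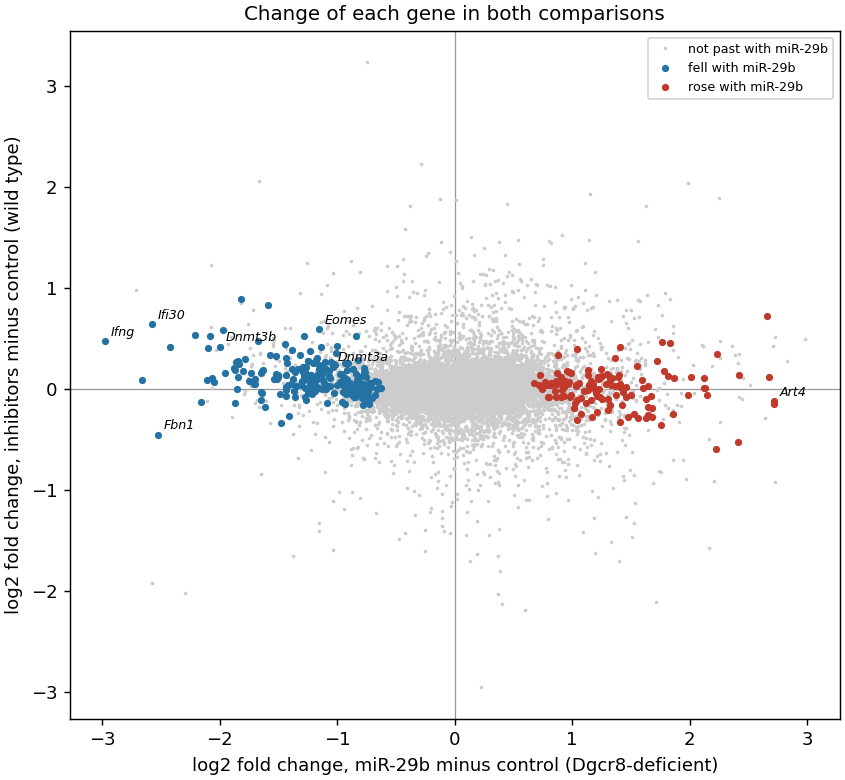
Log2 fold change of each of 14701 genes with miR-29b in Dgcr8-deficient cells (horizontal) and with inhibitors in wild-type cells (vertical), with genes past the threshold with miR-29b in blue (206 lower) and red (130 higher). Of the blue points, 157 lie above 0 on the vertical axis.

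Between the control cells of both genotypes, the largest rises in Dgcr8-deficient cells included interferon-related and B-lineage transcripts. These controls also received different oligonucleotides, a control miRNA and control inhibitors, so no difference between them can be credited to genotype alone. Dgcr8-deficient cells held more Apol7c (10.89 ± 0.62, at least 552-fold), Ubd (7.71 ± 0.49, at least 143-fold), Usp18 (6.96 ± 0.38), which restrains interferon signalling, Ido1 (6.71 ± 0.35), a tryptophan-degrading enzyme, and Ifng (6.32 ± 0.52). They also held more Jchain (7.93 ± 0.74), the joining chain of antibodies, Tns3 (6.45, at least 19-fold) and Rab6b (6.35, at least 33.2-fold). Eomes was higher by 4.62 ± 0.21, Tbx21 by 1.30 ± 0.59 without passing (adjusted p = 0.154, and 0.00168 with scan day as a block), and Dicer1 by 0.69 ± 0.22 (adjusted p = 0.0456, up to 0.168 without single arrays). Tbx21 passed in 2 of 13 alternative settings and not in the other 11 (limma, adjusted p up to 0.292). Drosha, Dnmt3a, Dnmt3b, Mcl1 and Tet2 were at -0.25, -0.09, 0.16, 0.34 and 0.30 and did not pass on their brightest probes, and the 2 other Dnmt3a probes gave 0.64 (adjusted p = 0.0241) and -0.31 (0.506). The deepest falls were in Zfp979 (-8.43 ± 0.27, at least 96.6-fold), Ifi202b (-7.34, at least 56.4-fold), Adh1 (-7.11), Mctp1 (-6.33, at least 37.1-fold), H2-T3 (-6.16), Lratd1 (-5.21), Morc1 (-4.85, at least 19.3-fold) and Tktl1 (-4.71).

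The comparison called 3216 genes, 1399 higher and 1817 lower in Dgcr8-deficient controls, with 4797 at an unadjusted p under 0.05. With slide and scan day as blocks 6130 and 5836 genes passed, on p-values that rest in large part on the spread within mice. Without a block, false calls made up 10.4% of calls in the simulated data for this comparison. Those data held 100 changed genes each of log2 1 and log2 2, so that share does not measure the false share of the 3216 real calls. Normexp moved the median of all genes to -0.22, against -0.07 here, so changes under that setting are relative to it. The lower bounds given for genes near background hold for the scaled signal alone. With normexp, whose offset shrinks changes of dim genes, Apol7c, Ubd, Tns3, Rab6b and Fbn1 were at 6.17, 4.17, 1.79, 2.09 and 1.41 and Zfp979, Ifi202b, Mctp1 and Morc1 at -3.93, -3.34, -2.76 and -2.08, each past the threshold. At their smallest across the alternative settings, H2-T3, Lratd1, Tktl1 and Adh1 were at -3.36, -2.56, -1.96 and -4.57, past the threshold each time. Of 98 named genes past the threshold 79 passed in all 6 fits without one array. The other 19, Dicer1, Il2ra, Tut4, Tyrobp and Fcer1g among them, reached adjusted p of up to 0.168.

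Of 35 interferon-stimulated genes 27 rose, 0 fell and 8 did not pass (29 higher adjusted over the list alone), with a median of 1.78 (camera adjusted p = 1.25e-22), 1.85 and 1.86 within the shared slides. Iigp1 (5.47), Gbp2 (4.54), Gbp3 (3.15) and Usp18 had the smallest p. Of 12 B cell markers 9 rose and 3 did not pass (10 higher adjusted over the list alone), with a median of 2.34 (camera adjusted p = 1.15e-08). The median was 2.53 and 3.19 within the shared slides, and 1.54 in the authors' values and 1.18 with normexp, past camera with both settings. The 9 genes included Blnk (6.26 ± 0.54), Ms4a1 (5.88 ± 0.58) and Cd79b (3.85 ± 0.34). Both lists also passed with an estimated correlation (adjusted p = 0.0422 and 0.0468), and no other list did. With scan day as a block 32 interferon-stimulated genes, 10 B cell markers and 14 p53 targets were higher, and 29 ribosomal protein genes and 13 cholesterol and fatty acid synthesis genes were lower.

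Of the Th1 and cytotoxic genes 12 rose, 2 fell and 14 did not pass (15 and 2 adjusted over the list alone, camera adjusted p = 1.22e-06, adjusted p = 0.187 with an estimated correlation), with Prf1 at 4.03 and Il12rb2 at 2.25. Curated miR-29 targets went both ways, with 8 higher, among them Fbn1 (5.63, at least 15.4-fold) and Bmf (2.97), 4 lower and 41 not past (8 and 4 over the list alone, adjusted p = 0.0173, 0.215 with an estimated correlation). Targets of other T cell microRNAs had 11 rises, 0 falls and 25 not past (12 and 3 over the list alone, 0.00248, 0.21 estimated), among them Maf (3.57), Zeb2 (2.73) and Tgfbr2 (1.47). p53 targets had 9 rises, 2 falls and 10 not past (10 and 2 over the list alone, 8.41e-05, 0.187 estimated), with Pmaip1 (2.37), Btg2 (1.85), Perp (1.77) and the cell cycle inhibitor Cdkn1a (1.31). NK cell markers had 3 rises, Cd244a (1.93), Tyrobp (2.57) and Fcer1g (1.17), and 6 not past (3 over the list alone, 0.0178, 0.492 estimated, 0.0551 without the Dgcr8-deficient control of mouse 4), and with normexp their median was -0.02 and did not pass (0.133).

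Ribosomal protein genes were lower in Dgcr8-deficient controls: 11 of 41 fell, 30 did not pass and 0 rose (19 lower adjusted over the list alone), with a median of -0.55 and Rpl14 at -1.66 (camera adjusted p = 1.08e-07, adjusted p = 0.491 with an estimated correlation). The median was -0.23 with quantile normalization and -0.36 in the authors' values, where that of all genes was -0.07 and -0.05. Cholesterol and fatty acid synthesis genes had 3 falls, Mvk at -1.62 first, 1 rise and 20 not past (3 and 1 over the list alone, adjusted p = 0.0301, 0.575 estimated). Apoptosis regulators had 4 rises, including Bmf, Bcl2l11 (1.53) and Apaf1 (1.21), 1 fall and 18 not past (4 and 1 over the list alone, 0.0499, 0.187 estimated). MicroRNA biogenesis genes had 6 rises, including Tarbp2 (1.33) and Tut4 (1.28), and 16 not past (6 over the list alone, 0.0408, 0.575 estimated). Each of these last 3 lists was lost in 4 of 6 fits without one array, with adjusted p up to 0.131, 0.0955 and 0.162. Their calls were also lost in 6, 3 and 6 of 15 alternative settings, the estimated correlation included.

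The remaining lists did not pass camera between the genotypes. The Treg list had Foxp3, its master regulator, lower (-1.70 ± 0.17) and Il2ra higher (1.31), with 2 rises, 2 falls and 6 not past (adjusted p = 0.716). CD4 T cell identity genes had Trat1 (-3.94), Cd40lg (-0.94) and 2 others lower, 1 higher and 11 not past (0.128). The Th17 list had 4 rises with Il21 at 3.10 (at least 3.43-fold) and 5 not past (0.0647), but Il21 was at 0.12 with normexp and 0.77 in the authors' values and did not pass in either. The Th2 list had 3 rises with Maf first, 2 falls and 9 not past (0.227), and the Tfh list had 1 rise, 1 fall and 7 not past (0.576, median -0.03 and mean 0.44). Naive and memory markers had 2 rises, Ccr7 (1.37) among them, and 10 not past (0.14), and T cell activation 5 rises with Irf4 at 1.88, 2 falls and 11 not past (0.0635). Rises and falls numbered 3 and 2 for cell cycle (0.843), 1 and 3 for DNA methylation (0.716), 2 and 3 for extracellular matrix (0.716, median -0.04 and mean 0.08), 4 and 4 for heat shock and unfolded protein response (0.843) and 2 and 5 for glycolysis (0.0635). They numbered 1 and 1 for CD8 markers (0.376), 2 and 3 for myeloid markers (0.997, median 0.01 and mean -0.04) and 0 and 0 for erythroid and platelet markers (0.997). Of these lists, the counts adjusted over the list alone differed for glycolysis (10 falls), T cell activation (7 rises), Tfh (2 rises) and Th17 (1 fall).

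**Figure D4:**
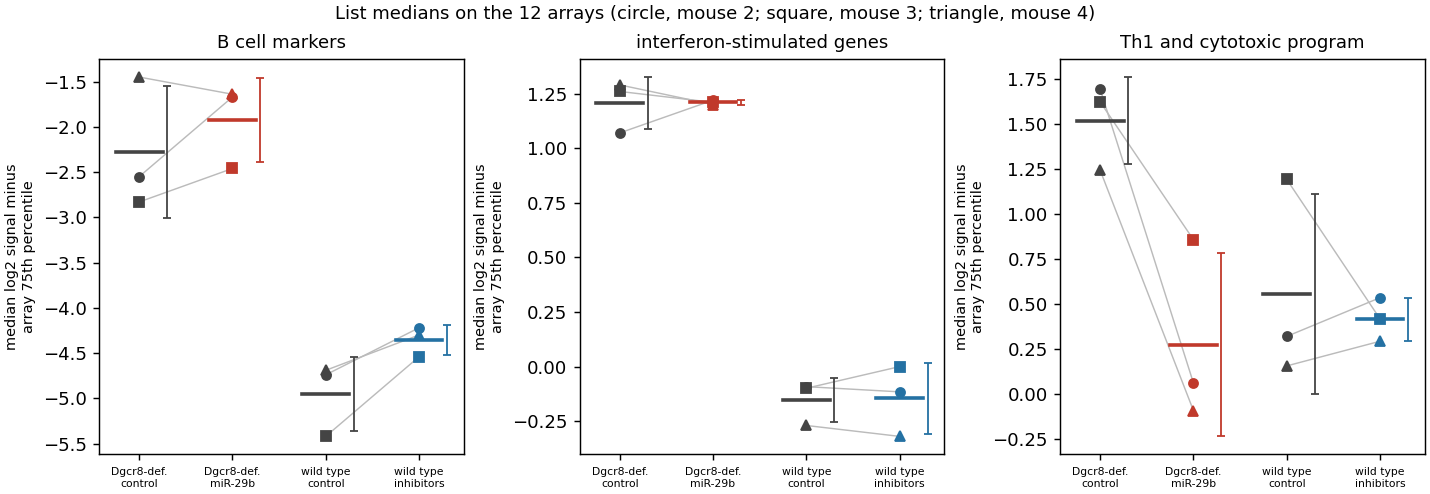
Median level of B cell markers, interferon-stimulated genes and Th1 and cytotoxic genes on each of the 12 arrays, as log2 signal minus the 75th percentile of the array, with lines joining the arrays of one mouse, bars at group means and error bars of 1 SD. B cell markers lie at -2.83 to -1.45 in Dgcr8-deficient arrays and lower in the wild type, and the median level of interferon-stimulated genes does not show the median change of -0.40 of the single genes with miR-29b.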

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

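The test for B cells in a single culture and the test of an intensity trend as the whole rise were chosen after the result was seen.

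The effects of miR-29b and of the inhibitors differed by the test of the difference itself for 28 genes. Among them the difference, as the miR-29b effect minus the inhibitor effect in log2, was -3.21 for Ifi30, -2.74 for Dcakd, -2.71 for Ccdc28b, -2.60 for Serf1, -2.55 for Ccn4, -2.42 for Srd5a1, -2.41 for Dnmt3b and -2.15 for Zbtb34. It was -2.12 for Fgl2, -2.08 for Pigc, -2.08 for Ssr2, -2.07 for Bak1, -1.88 for Klhdc3, -1.85 for Tmem189, -1.82 for Eif4e2, -1.75 for Fh1, -1.75 for Narf and -1.67 for Taf13. For Septin2, Fem1b, Atxn7l3b, Xdh, Rps6ka4 and Snrpd2 it was -1.57, -1.56, -1.52, -1.47, -1.44 and -1.27, and for Lefty1, Gpr179 and Art4 1.75, 1.96 and 2.84. Of 100 splits of the arrays within genotypes, 4 gave as many genes, the real split included, with 28 for the real split and 74 for the highest other, a share under 0.05. Among the 16 splits that put both arrays of every mouse in different groups, as the real one did, the highest other gave 17. The 3 other splits with as many all kept the real miR-29b groups, so they still held the miR-29b effect, which the splits that regrouped Dgcr8-deficient arrays broke up, and they put both arrays of some mice in one group. With the mouse as a block the real split gave 888 genes and 3 of 16 swaps within mice gave as many, at most 1705, and 16 swaps are too few for a share under 0.05. Whether the number of these genes exceeds a random grouping therefore stays open.

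Of 10675 probes without a gene symbol, which the comparisons of named genes did not use, 7 passed the threshold with miR-29b and 1207 between the genotypes.

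The 130 genes that rose with miR-29b included many dim ones, and with all genes ranked by intensity into 10 equal groups the median change was 0.34 in the dimmest group, against -0.0012 in the sixth. Over all 130 the median rise was 1.23 (SD 0.46) before a loess correction over intensity and 1.16 (SD 0.398) after it. The genes had been chosen for a large rise, and the trend reached 0.34 in the dimmest group. A correction of that size could not remove the whole rise, so this shows only that the trend was smaller than the rise. The correction moved the dimmest group from 0.34 to -0.06, and 137 rises passed after it. These held 101 of the 130 (77.7%), a share between the bounds set beforehand, which alone decides nothing. For the other 29 the median was 1.24 before and 1.08 after (SD 0.378), so most of the rise stayed while the call ended. Normexp kept 58 of the 130, and Ric3, Ces2e and Chl1 shrank below 0.5 with it. An effect of miR-29b on these genes stays open as a hypothesis.

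B-lineage transcripts were higher in Dgcr8-deficient controls. If B cells were left in the cultures, other B-lineage genes should be higher too, and 12 of 18 further ones were (66.7%, against 9.52% of all genes, camera p = 7.98e-08, p = 0.00812 with an estimated correlation). The abundant transcripts Jchain and Cd74 were at 1.85 and 2.90 in these controls and -6.08 and -1.89 in the wild type, and Cd79a was higher by 1.46 ± 0.20 (limma, adjusted p = 0.000661), while Pax5 and Cr2 differed by 0.02 and -0.19. A source in one culture alone is argued against, since 10 of 12 markers had all Dgcr8-deficient controls above all wild-type controls. Most of these markers had already been called higher on the same arrays, and markers can vary together. The 5% that chance gives a single gene in this direction is therefore no measure of this count. Residual B cells are thus a candidate source, expression of these genes in Dgcr8-deficient T cells remains untested, and the labels name no sort beyond helper T cells.

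Kcnf1, Mctp1, Ankrd22, Sgms2, Zfp979, Kel, Hpgds and Dock1 were near background only in Dgcr8-deficient cells, and 26 genes only in the wild type. All 8 genes still passed without the control array of mouse 3. They had been chosen as near background on every Dgcr8-deficient array, those of the other mice included. That result was therefore set by the choice and is no test of the sex of mouse 3. Mice 2 and 4 had Y-linked medians of -0.13 to 0.82, against -0.32 to 0.43 in the wild type. The 8 genes were near background in those mice as well, which argues against the sex of mouse 3 as the reason. Of the 8 genes, 0% lay on the chromosome of Dgcr8, which argues against a segment carried along with the targeted allele. Segments of another strain elsewhere may still be present. These genes held 0 neighbouring pairs, but random sets averaged only 0.0416 (permutation p = 1), so the test had no room to fall below chance and leaves this open. A direct effect of the deficiency was not tested.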

How the results depend on the processing

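Fits without Dgcr8-deficient mouse 3, on the first scan day only and with the mouse block combined with another choice, and normexp on the median signal, were chosen after seeing the data. The count of genes changed by miR-29b was 336, and it was 3074 with the mouse as a block, 2466 and 1840 with slide and scan day as blocks, 568 with the authors' values, 3735 with the block and the authors' values and 1813 with the block and without mouse 3. It fell to 116 without mouse 3, 98 on the first scan day (where fewer arrays were fitted), 0 in a fit of its own arrays (1358 at an unadjusted p under 0.05) and 103 to 276 without single arrays. It stayed within 1.5 times with normexp, quantile normalization, the filters on dim probes, the trended variance model, the mean of probes and every probe separately, and of the 336 calls 313 were kept with quantile normalization, 308 with the authors' values and 225 with normexp. The inhibitor count was 0 in every fit run. The genotype count of 3216 became 6130 and 5836 with slide and scan day as blocks, 3219 with the replicate number as a block although the numbers do not pair mice, and 2319 to 2733 without single arrays.

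The count of genes with different effects, 28, became 888 with the mouse as a block, 617 and 446 with slide and scan day as blocks, 1593 with the block and the authors' values and 616 with the block and without mouse 3. It was 93 with the authors' values (23.7% higher, against 10.7%), 62 with probes well above background on all arrays, 59 with the trended variance model, 14 with the mean of probes, 15 without mouse 3, 0 on the first scan day and 3 to 51 without single arrays. Normexp moved the median of all genes to 0.15 in this comparison, against 0.06. The cause of these shifts was not tested, beyond the smaller number of arrays where arrays were left out.

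With an estimated correlation 0 of 9 lists passed for miR-29b, 0 of 8 for the inhibitors, 2 of 11 between the genotypes and 0 of 9 for the difference, and with fry 5, 0, 13 and 3. The inhibitor count of lists was 3 on the first scan day and 1 to 6 without single arrays, and the other counts were 7 to 10, 8 to 12 and 7 to 10. Ric3 turned to -0.27 with the authors' values, with and without the mouse as a block. The inhibitor median of ribosomal protein genes ran from -0.0155 to 0.18 without single arrays, and was 0.0066 with quantile normalization. The correlation of both effects stayed within its spread over splits (SD 0.233) in every setting. The shift of genes by miR-29 sites was not run. Signal over background limits the dim genes, and the rises of Ric3, Ces2e and Chl1 fell below 0.5 with normexp.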

Other observations

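The tests of genes chosen in the first paragraph here were made after their values were seen, as were the look-up of miR-29b calls in the inhibitor comparison and the miR-29 targets without Th1 genes.

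Among genes chosen after their values were seen, Cd74, the invariant chain of MHC class II, was higher in Dgcr8-deficient controls by 4.79 ± 0.34, H2-Aa by 5.10 ± 0.35, H2-Ab1 by 2.68 ± 0.27 and the class II regulator Ciita by 1.99 ± 0.28 (limma, adjusted p = 1.4e-05, 1.03e-05, 8.9e-05 and 0.000679). These 4 genes were not tested as a group, B cells also express them, and B cell markers were higher in the same controls (median 2.34, 9 of 12 past the threshold). Cd274, the ligand of PD-1, was higher by 3.40 ± 0.41, and the chemokine receptor gene Ccr2 and the transcription factor gene Id3 were lower by -3.39 ± 0.67 and -3.02 ± 0.42. With miR-29b, Gzmm, a granzyme, fell by 1.85 ± 0.32 and Hopx by 2.05 ± 0.38 on the log2 scale.

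Curated miR-29 targets without the Th1 genes Tbx21, Eomes and Ifng kept 50 members, of which 7 fell with miR-29b (unadjusted camera p = 2.07e-05, unadjusted p = 0.0116 with an estimated correlation). In the inhibitor comparison this list had an unadjusted camera p = 0.0225 and p = 0.119 with an estimated correlation. The camera p of 0.162 for the full list with an estimated correlation was adjusted over all lists. The unadjusted 0.0116 therefore does not show that dropping these genes makes the list pass.

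A hypothesis was that lower Dnmt3a and Dnmt3b may release germline genes silenced by DNA methylation, and so account for some of the rises with miR-29b. Of 38 such genes 16 were measured, with a median of 0.351 after the intensity correction and 12 of them positive, 0 passing singly and 2 with the mouse as a block. The list did not pass camera (p = 0.0783, p = 0.0981 with an estimated correlation), so the median and the test point apart and the hypothesis stays undecided. DNA methylation was not measured here.

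With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For miR-29b 1 of 10 splits gave as many genes as the real 336, with 0 for the highest other, and between the genotypes 1 of 10 gave as many as 3216, also with 0 for the highest other. For the inhibitors 10 of 10 gave at least the real 0, and the highest other gave 1. For miR-29b with the mouse as a block, 4 swaps of arrays within mice were possible. The real one gave 3074 genes and every other gave 0, but 4 swaps are too few for a share under 0.05. Of the lists, 4 of 10 splits gave as many as the 9 for miR-29b (highest other 13). The 3 others with as many put both arrays of 2 mice in one group, and the 3 others that parted all mice, as the real one did, gave 6 each. For the inhibitors 1 of 10 splits gave as many as the 8 lists (highest other 3, in splits that parted all mice), and between the genotypes 2 of 10 as many as the 11 (highest other 12). For the difference 18 of 100 splits gave as many lists as the real 9, with 16 for the highest other, so a random grouping was not excluded. Among the 16 splits that parted every mouse 3 gave as many, with 9 for the highest other, and all 3 held the real miR-29b groups, while the other 15 with as many put both arrays of 2 or more mice in one group. These 16 are too few for a share under 0.05. A random grouping was also not excluded for the correlation of both effects, where 90 of 100 splits lay as far from 0 as -0.02, with 0.65 for the highest other. Of the 206 genes that fell with miR-29b, 157 were higher with inhibitors, 2 of 10 splits of the wild-type arrays moved as many one way and the highest other, which also parted all mice, moved 169.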
